A study of Arabidopsis thaliana with 6 samples.

How the data were processed

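Whole seedlings of Arabidopsis Col-0 and of a line labelled as an epl1a epl1b double mutant were sampled, 3 libraries per genotype, from plates with 1% sucrose after 3 days of cold treatment of the seed at 4 °C, under light of 100 µmol per square metre and second. Per the labels' protocols, libraries were made from total RNA after depletion of plant ribosomal RNA with a stranded kit, and a minimum of 40 M single-end reads of 50 bases were sequenced per library. The submitters' processing notes name the TAIR10 build and DESeq2, with no version. The aligner, the read counter and whether counting used the strand are not given in the sources used here.

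The authors deposited 2 tables, of genes higher and lower in the libraries labelled as the mutant. Per the file headers they hold raw read counts of each gene in each of the 6 libraries, a p-value and a false discovery rate, and a log2 fold change of mutant over wild type. Tested on the values, every listed gene had an absolute log2 fold change of at least 1 and a false discovery rate under 0.05 in the authors' deposited tables, so genes that missed these thresholds are not analysed here. The tables hold 5330 genes. The p-value is listed at 0 for 996 of them. Symbols shared by several genes had given 14 rows the locus of another gene, and these were reassigned by exact match of the start and end to the reference annotation. Of 5297 nuclear genes matched to the TAIR10.1 annotation used here, 98.57% had the same start and end. Coordinates are printed as the deposited tables give them.

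Because the tables hold selected genes, a normalisation that assumes most genes unchanged has no footing in them. The authors' between-library scaling was recovered from their log2 fold changes instead: 5 relative factors were fitted by least squares to the 1774 genes with at least 200 reads in every library. The median absolute residual was 0.00029 log2 units. The factors were 1.0, 0.931 and 0.820 for Col-0 replicates 1 to 3 and 1.16, 1.04 and 1.20 for mutant-labelled replicates 1 to 3, with a largest bootstrap SE of 0.00124 over 50 draws. Normalised reads are counts divided by these factors. Using them in place of TMM departs from the plan and was chosen after seeing the data. TMM factors and DESeq2 size factors of the listed genes shift log2 fold changes by -0.47 and -1.11. Fewer genes are then called higher, and the smallest rises can fall below 0, by construction. Such losses show dependence on the scaling and are not separate evidence on the direction of a gene.

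Counts were tested with edgeR 4.0.16 (quasi-likelihood, limma 3.58.1, R 4.3.3) with the recovered factors as library sizes, the edgeR expression filter, no replicate block, and Benjamini-Hochberg adjustment over the 4773 genes that passed the filter. The filter left out 557 genes. All 4773 genes in the fit were called, so adjustment over a list alone could not lose a call and is no check. The genes had been selected on the same libraries, so an edgeR adjusted p does not control false calls over all expressed genes. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Gene lists, 27 in number with 533 members, the tests and the rule for naming genes were fixed before the data were examined. The rule took listed NuA4 subunits, every listed chloroplast and light regulator, and the 5 genes with the largest change in each direction among those with an adjusted p under 0.05 and a mean level above the median of that direction. It added, for each list with at least 5 listed members, the 2 with the largest change in the majority direction and the 1 with the largest in the other. Other genes are named where a list is small or to say which genes a count holds, after their values were seen.

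The direction of a list was tested with Fisher's exact test, two-sided, of members listed higher and lower against all other listed genes, adjusted over 25 lists with at least 3 listed members. The share of a list was tested with the same test against the other protein-coding genes of the annotation, 27529 in all, adjusted over 54 list and direction pairs; this background includes genes not expressed in seedlings and so favours expressed lists. Both tests treat genes as independent, and no test that allows for correlation between genes was run. The sizes of changes were compared with a permutation test of 100000 resamples, or 10000 for alternatives. It permutes genes, so it also treats them as independent and does not measure the spread between libraries. A fold against 0 reads was set against a floor of 3 counts over the group, and ratios over 1 to 3 reads have 95% exact binomial intervals; both cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

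The edgeR step was tested on simulated counts of the same genes and libraries, with 4778 genes in the fit. It recovered 38.1% of 97 genes changed 2-fold and 90.6% of 96 genes changed 4-fold, with 4.6% false calls and 0 sign errors among calls. The other simulated genes were unchanged, whereas the real genes had all been selected as changed. These rates therefore do not describe the calls on the real counts. The list test recovered 100.0% of 200 planted lists of 12 genes and called 0.45% of random ones, on 5330 genes. The planted lists were made almost wholly of lower genes, so this recovery covers leans lower alone. Leans higher were not simulated. They are harder to reach, because 33.9% of all listed genes were lower. Alternatives were stricter thresholds, genes above the median mean level, DESeq2 1.42.0 with the recovered factors or its own, no count filter, each library left out, a replicate block, other backgrounds and, added after seeing the data, TMM factors of the listed genes and mutant-labelled replicate 1 alone against Col-0, where the spread between libraries comes from Col-0 alone. Replicates of a group differed beyond sampling noise: chi-square per gene was 15.7 to 16.6 between Col-0 libraries, 18.1 between mutant-labelled replicates 2 and 3, and 119.5 and 169.0 between replicate 1 and those.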

Results

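RNA was sequenced from whole Arabidopsis thaliana seedlings of wild type Col-0 and of a line labelled as an epl1a epl1b double mutant. EPL1A and EPL1B are the Arabidopsis copies of Enhancer of Polycomb, a subunit of NuA4, the complex that acetylates histone H4. The series title sets the question: how NuA4 acts on nuclear and plastid transcription during chloroplast formation. Each genotype had 3 libraries, from 3 independent experiments according to the design text. Seedlings were 14 days old and were taken 8 h after dawn in a day of 16 h light and 8 h dark at 22 °C. The 2 tables used here hold the genes that passed the authors' thresholds, with 3524 listed higher and 1806 listed lower in the libraries labelled as the double mutant, and the reads of each listed gene in each library. Reads in listed genes came to 10938542, 10557724 and 9265086 in Col-0 replicates 1, 2 and 3, and to 7531211, 7355421 and 8625707 in replicates 1, 2 and 3 of the line labelled epl1a epl1b. These sums cover the listed genes and are not library depths. Levels below are normalised reads, that is reads divided by each library's scaling factor relative to Col-0 replicate 1.

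The targeted genes moved in opposite directions. EPL1A (AT1G16690, chromosome 1, 5705897 to 5709563, plus strand, TAIR10) fell from 367.2 ± 9.59 to 124.5 ± 3.34 normalised reads (SD, n = 3 per group), a log2 fold change of -1.56 ± 0.11 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.34e-06). EPL1B (AT1G79020, chromosome 1, 29727044 to 29730593, minus strand) rose from 719.5 ± 57.5 to 17051 ± 69.3 normalised reads (SD, n = 3 per group). Its log2 fold change was 4.57 ± 0.09 (SE; edgeR quasi-likelihood, adjusted p = 9.12e-07), and its level was 17029, 16995 and 17128 in the 3 libraries labelled as the mutant. Each gene has a single read count per library, which does not show where in the gene the reads lie. Where the alleles interrupt the genes is not given in the sources used here. The rise therefore does not show an intact EPL1B transcript. Because EPL1B goes against its label, the libraries are called epl1ab-labelled from here on, and every direction below is drawn between labels. One other NuA4 subunit was in the tables: YAF9B, a YEATS-domain protein, rose from 71.8 ± 7.85 to 185.7 ± 8.45 normalised reads (log2 fold change 1.37 ± 0.15 SE, edgeR adjusted p = 6.72e-05, n = 3 per group). edgeR called 2 NuA4 genes higher and 1 lower, which adjustment over the list alone could not change. The other 15 members were not in the tables. DESeq2 with the recovered factors called the same counts, and DESeq2 with size factors from the listed genes called 1 higher and 1 lower, with YAF9B at a log2 fold change of 0.25 (adjusted p = 0.371).

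**Figure D1:**
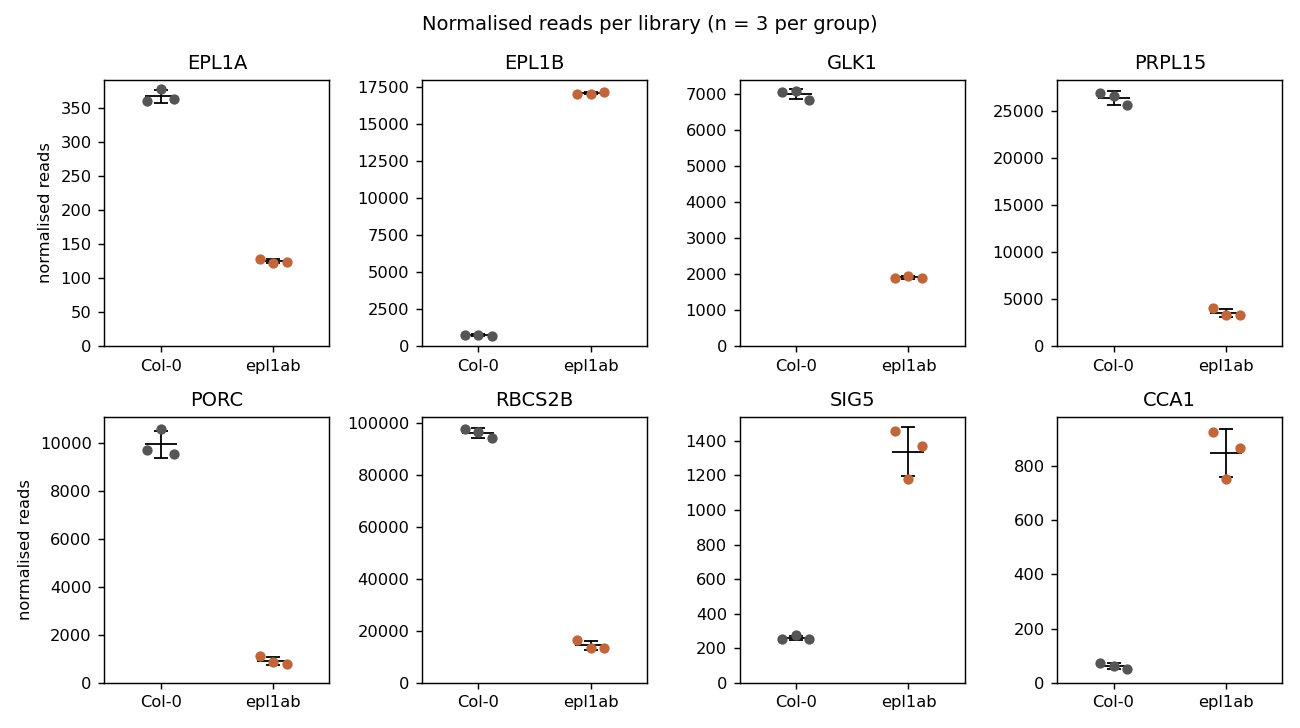
Normalised reads (y axis, linear, each panel with its own scale) of 8 genes in Col-0 and epl1ab-labelled libraries (x axis); points are the 3 libraries of each group, horizontal lines the mean and bars 1 SD. EPL1A, GLK1, PRPL15, PORC and RBCS2B lie lower in all 3 epl1ab-labelled libraries, and EPL1B, SIG5 and CCA1 lie higher.

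Genes of the chloroplast were mostly on the lower side. Among nuclear genes, the authors listed as lower 29 of 31 plastid ribosomal proteins, 18 of 22 components of the plastid transcription machinery, 20 of 25 photosystem subunits, 18 of 26 tetrapyrrole and chlorophyll synthesis genes and 13 of 22 light-harvesting antenna proteins. They also listed as lower 6 of 10 electron transport and ATP synthase genes and 6 of 19 Rubisco and Calvin cycle genes. Of these lists, a single member was listed higher, SIG5, a light- and stress-responsive plastid sigma factor. Each of these lists leaned lower against all other listed genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 25 lists); of all listed genes 33.9% were lower. The adjusted exact p was 5.04e-13 for plastid ribosomal proteins, 2.65e-07 for the transcription machinery, 4.64e-09 for photosystem subunits, 2.73e-08 for tetrapyrrole synthesis, 3.14e-06 for antenna proteins, and 0.0047 for each of the electron transport and Calvin cycle lists. Both of the last lists lost the lean among genes above the median mean level (exact adjusted p = 0.0519). Each kept 6 lower and 0 higher members there, but a larger share of the listed genes was lower.

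The plastid ribosomal proteins had a median log2 fold change of -2.14 in the authors' deposited table, against -1.66 for the plastid transcription machinery and -1.34 for photosystem subunits. PRPL15, a protein of the large plastid ribosomal subunit, fell from 26345.5 ± 706.7 to 3533.5 ± 415.2 normalised reads (SD, n = 3 per group), 7.46-fold by edgeR (log2 fold change -2.90 ± 0.105 SE, adjusted p = 9.12e-07). PRPL11 fell 6.57-fold (log2 fold change -2.72 ± 0.10 SE). PTAC7 and PTAC14, proteins attached to the plastid-encoded RNA polymerase, fell 5.07-fold and 4.81-fold. SIG5 rose from 261.2 ± 11.04 to 1335 ± 142 normalised reads (SD, n = 3 per group), a log2 fold change of 2.35 ± 0.11 (SE; edgeR adjusted p = 2.04e-06). edgeR called 29 ribosomal protein genes lower, and 18 transcription machinery genes lower with 1 higher. Adjustment over each list alone could not change these counts, since every gene in the fit was called.

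The median log2 fold change in the authors' deposited table was -1.75 for tetrapyrrole and chlorophyll synthesis genes, -1.45 for antenna proteins, -1.26 for electron transport and ATP synthase genes and -1.29 for Calvin cycle genes. PORC, a light-dependent protochlorophyllide reductase, fell from 9927 ± 575 to 920.5 ± 169.7 normalised reads (SD, n = 3 per group), 10.8-fold by edgeR (adjusted p = 1.31e-06). GSA2, which makes 5-aminolevulinate, fell 6.15-fold. LHCA6, a minor antenna protein of photosystem I, fell 9.97-fold and LHCB1.4, a major antenna protein of photosystem II, fell 5.28-fold. PSBQA of the oxygen-evolving complex fell 3.41-fold and PSBTN, a small photosystem II subunit, fell 3.26-fold. FNR1, the leaf ferredoxin-NADP reductase, fell 2.91-fold, and ATPG of the plastid ATP synthase fell 2.62-fold. RBCS2B, a Rubisco small subunit gene, fell 6.65-fold, and HCEF1, the plastid fructose-1,6-bisphosphatase, fell 3.57-fold. LHCB1.4 and RBCS2B have close paralogs that can share 50-base reads, so their individual values are uncertain. edgeR called 18 tetrapyrrole, 13 antenna, 20 photosystem, 6 electron transport and 6 Calvin cycle genes lower and 0 higher. Adjustment over each list alone could not change these counts.

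The regulators of chloroplast and light responses were divided. GLK1, a transcription factor that activates photosynthesis genes, fell from 7008 ± 133 to 1911 ± 38.1 normalised reads (SD, n = 3 per group; log2 fold change -1.87 ± 0.06 SE, edgeR adjusted p = 9.12e-07). The bZIP factors HY5 and HYH, which promote light-dependent development, rose by a log2 fold change of 1.15 ± 0.15 and 2.32 ± 0.18 (SE). CGA1, a GATA factor that promotes chloroplast development, rose by 1.39 ± 0.17 (SE, log2). edgeR called 3 higher and 1 lower, which adjustment over the list alone could not change. The other 10 of 14 members were not in the tables. DESeq2 with size factors from the listed genes called 1 higher and 1 lower, against 3 and 1 with the recovered factors, and did not call HY5 (log2 fold change 0.04, adjusted p = 0.848) or CGA1 (log2 fold change 0.28, adjusted p = 0.275). No lean was detected (exact adjusted p = 1).

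Transcripts of the plastid genome were listed as lower and none as higher. The authors listed 32 plastid genes lower and 0 higher, against 1774 nuclear genes lower and 3524 higher (Fisher's exact test, two-sided, p = 7.59e-16). No mitochondrial gene was in the tables. Of 27 plastid-encoded photosynthesis genes 15 were lower (exact adjusted p = 4.29e-07), and of 29 plastid genes for gene expression and housekeeping 5 were lower (exact adjusted p = 0.0111). The share of the housekeeping list, 17.2% lower against 6.39% of other genes, was not called (exact adjusted p = 0.0945). psbK fell from 18.2 ± 2.21 to 3.42 ± 2.95 and psbF from 31.1 ± 8.39 to 6.73 ± 2.47 normalised reads (SD, n = 3 per group), with edgeR adjusted p of 0.0025 and 0.000617. rpl32 fell 4.61-fold and rps4 fell 2.82-fold by edgeR. These reads are few, 50 over the 3 Col-0 libraries for psbK, so each fold rests on low counts. Reads were also few over the list: the 15 listed plastid photosynthesis genes summed to a Col-0 mean of 6233.5 normalised reads. The 13 listed nuclear antenna genes summed to 2090275. How fully the counts sample plastid transcripts is not known, so the plastid results hold for the counts as given. Without epl1ab-labelled replicate 3 the edgeR log2 fold change of psbK went from -2.33 to -3.24. edgeR called 15 and 5 members lower, which adjustment over each list alone could not change. Of the plastid genes, 7 had a mean level above the median of all listed genes, where the exact p of genome against direction was 0.016 and the photosynthesis list no longer leaned (exact adjusted p = 0.0874); 0 housekeeping members were above that median.

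**Figure D2:**
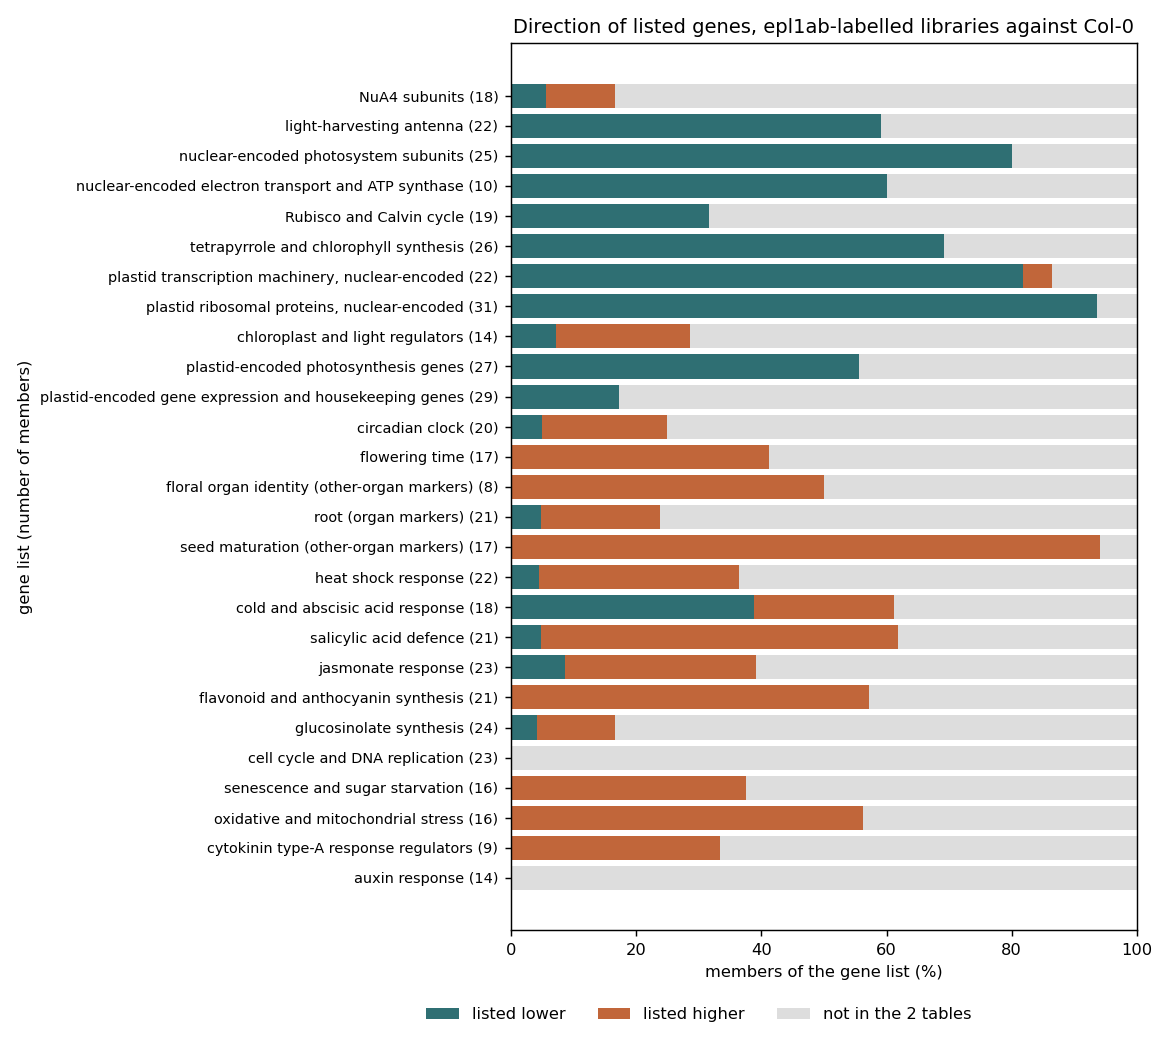
Share of each gene list (x axis, percent of members; members in brackets on the y axis) that the authors listed lower or higher in epl1ab-labelled libraries, or that was not in the 2 tables. The plastid ribosomal protein list is 93.5% lower and the seed maturation list 94.1% higher.

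Seed maturation genes were listed higher, and the epl1ab-labelled libraries differed in them. The authors listed 16 of 17 seed maturation genes higher and 0 lower, with a lean against the other listed genes (exact adjusted p = 0.00622). They include the storage proteins CRA1 and SESA1, the oleosins OLEO1 and OLEO2, the late embryogenesis protein EM1, and the embryo regulators ABI3, FUS3, LEC1 and LEC2. Summed over the 16 genes, normalised reads were 411, 374.9 and 43.9 in the Col-0 libraries, and 1175.5, 205423 and 297887 in epl1ab-labelled replicates 1, 2 and 3. EM1 had 1 read over the Col-0 libraries and 3135 over the epl1ab-labelled ones, a ratio of 2550 after scaling with a 95% exact binomial interval of 457 to 101000, which covers counting error only. Its normalised reads were 12.1, 852 and 1873 in epl1ab-labelled replicates 1, 2 and 3. SESA1 went from 16.6 ± 14.5 to 16422 ± 16416.5 normalised reads (SD, n = 3 per group; edgeR adjusted p = 0.00336), with 48.5 in replicate 1. In that replicate alone against Col-0, the log2 fold change of SESA1 was 1.497. SESA1 is 1 of the 16 listed members, and their sum of 1175.5 in replicate 1 lay above each Col-0 sum. Without epl1ab-labelled replicate 3 the edgeR log2 fold change went from 9.895 to 8.89 for SESA1 and from 10.88 to 9.78 for EM1, whose Col-0 read lay in replicate 2. The SESA genes are close copies of one another and their single values are uncertain. edgeR called 13 members higher, which adjustment over the list alone could not change, and 15 without epl1ab-labelled replicate 1.

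**Figure D3:**
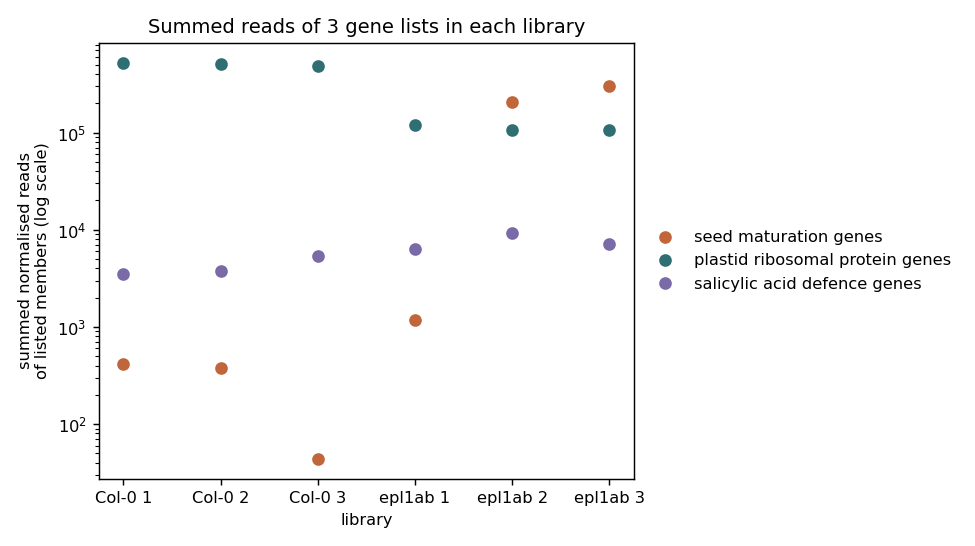
Normalised reads summed over the listed members of 3 gene lists (y axis, log scale) in each of the 6 libraries (x axis); each point is 1 library. Seed maturation genes reach 205423 and 297887 in epl1ab-labelled replicates 2 and 3 and 1175.5 in replicate 1, while plastid ribosomal protein genes lie between 105901 and 119996 in all 3.

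Genes with the largest rises at higher mean levels followed the same library pattern. Besides EM1 they were AT2G05580, described as a glycine-rich protein, AT5G55410, described as similar to lipid-transfer and 2S albumin proteins, AT1G54860, a GPI-anchored glycoprotein, and AT3G63040, which has no described function. AT3G63040 and AT5G55410 had 0 reads in all Col-0 libraries, and their levels were at least 313-fold and at least 290-fold higher against a floor of 3 counts over the Col-0 group. AT2G05580 had 2 Col-0 reads in all, a ratio of 2660 with an interval of 737 to 22000, and AT1G54860 had 1, a ratio of 1340 with an interval of 240 to 53000. These 4 genes had 7.79, 7.79, 5.19 and 0.87 normalised reads in epl1ab-labelled replicate 1, in the order AT2G05580, AT5G55410, AT1G54860 and AT3G63040. They did not pass the edgeR count filter, and their choice rests on the authors' adjusted p. Across the tables, 159 genes were over 8-fold higher in both replicates 2 and 3 than in replicate 1, and 1 gene was over 8-fold higher in replicate 1 than in both others.

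At the other end, the largest falls at higher mean levels were seen in all 3 epl1ab-labelled libraries. The gene ndhN (AT5G58260, chromosome 5, 23560568 to 23562001), a subunit of the plastid NADH dehydrogenase-like complex, fell from 3835 ± 50.5 to 24.4 ± 9.02 normalised reads (SD, n = 3 per group), 155-fold by edgeR (adjusted p = 9.12e-07). XDH2, a xanthine dehydrogenase of purine breakdown, fell 60.4-fold. COR413IM1, a cold-regulated protein of the chloroplast inner envelope, fell 31.0-fold. AT4G12830 fell 26.2-fold and AT5G59250, described as a plastid xylose-proton symporter, fell 20.7-fold.

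Members of 4 stress and defence lists were listed higher more often than other protein-coding genes. A lean higher against the other listed genes was not called for any of these lists. Since 33.9% of all listed genes were lower, that test has little power for short lists on the higher side. The senescence list, with 6 higher and 0 lower, could give no smaller exact p on that side than its 0.103 before adjustment. The authors listed 12 of 21 salicylic acid defence genes higher and 1 lower, and 57.1% of the list among genes listed higher compares with 12.2% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 6.92e-06 over 54 tests). The direction lean of the list was not called (exact adjusted p = 0.131), but was called among genes above the median mean level (exact adjusted p = 0.0392) and with TMM factors of the listed genes (exact adjusted p = 0.0415). PR1, a defence marker, rose from 37.3 ± 10.2 to 1859 ± 1164 normalised reads (SD, n = 3 per group), 49.8-fold by edgeR (adjusted p = 4.58e-05), with 793.8, 3101 and 1682 in the epl1ab-labelled libraries. Without epl1ab-labelled replicate 2 the edgeR log2 fold change of PR1 went from 5.64 to 5.05. WRKY38 rose 23.8-fold from 8 reads over Col-0, with 2.0, 0 and 7.32 normalised reads in the Col-0 libraries, and its edgeR log2 fold change of 4.57 was 3.98 without Col-0 replicate 2 and 5.98 without Col-0 replicate 3. PAD3, an enzyme of camalexin synthesis, fell 2.99-fold. The oxidative and mitochondrial stress list had 9 of 16 members higher and 0 lower (share, exact adjusted p = 0.000156; lean, exact adjusted p = 0.0691). Its lean was called in the same 2 settings (exact adjusted p = 0.00734 and 0.0339) and with replicate 1 as the only epl1ab-labelled library (exact adjusted p = 0.0336). Of its members BAP1 rose 5.42-fold and GSTU25 rose 2.92-fold; with size factors from the listed genes, NAC013 and AOX1A were below 0. With those size factors DESeq2 called 4 defence and 1 oxidative stress genes higher, against 12 and 9 with the recovered factors, and neither share was called (exact adjusted p = 0.110 and 0.958).

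Heat shock genes had 7 of 22 higher and 1 lower (share, exact adjusted p = 0.04235; lean, exact adjusted p = 0.411). HSP21, a plastid small heat shock protein, had 1 read over Col-0 and 92 over the epl1ab-labelled libraries, a ratio of 74.7 with an interval of 13.1 to 2980, and its Col-0 read lay in replicate 2. HSP23-6 rose 18.3-fold from 10 reads over Col-0, with 2.0, 6.45 and 2.44 normalised reads in the Col-0 libraries, and its edgeR log2 fold change went from 4.19 to 4.88 without Col-0 replicate 2. HSP15-7, a peroxisomal protein, fell 5.43-fold. Senescence and sugar starvation genes had 6 of 16 higher and 0 lower (share, exact adjusted p = 0.0328; lean, exact adjusted p = 0.162), with SAG21 5.02-fold and ASN1 3.29-fold higher; NAC019 and DIN2 were below 0 with size factors from the listed genes. Against the genes of the fixed lists alone, neither share was called (exact adjusted p = 0.213 for heat shock and 0.142 for senescence). Both were also lost without Col-0 replicate 1 (exact adjusted p = 0.0876 and 0.0822) and at an authors' adjusted p under 0.01 (exact adjusted p = 0.205 and 0.0799), and the heat shock share also without Col-0 replicate 2 or epl1ab-labelled replicate 2 (exact adjusted p = 0.0879 and 0.0705). Above the median mean level the heat shock share was not called (exact adjusted p = 0.657), and with replicate 1 as the only epl1ab-labelled library neither was (exact adjusted p = 0.0512 each). With TMM factors and with size factors of the listed genes, the heat shock share had an exact adjusted p of 0.172 and 0.382, and the senescence share of 0.0592 and 0.666. edgeR called 12 defence, 9 oxidative stress, 7 heat shock and 6 senescence genes higher. Adjustment over each list alone could not change these counts. With size factors from the listed genes DESeq2 called 3 heat shock and 2 senescence genes higher, against 7 and 6 with the recovered factors.

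Of the flavonoid and anthocyanin synthesis genes, the authors listed 12 of 21 higher and 0 lower, and the other 9 were not in the tables. The list had a lean (exact adjusted p = 0.0256) and a share above that of other genes (exact adjusted p = 6.92e-06); with size factors from the listed genes TT8, GL3 and DFR were below 0. MYB90, an activator of anthocyanin synthesis, had 2 reads over Col-0 and 87 over the epl1ab-labelled libraries, a ratio of 35.3 with an interval of 9.49 to 296; both Col-0 reads lay in replicate 3. MYB12, an activator of flavonol synthesis, rose from 94.8 ± 14.6 to 472 ± 121 normalised reads (SD, n = 3 per group; log2 fold change 2.32 ± 0.235 SE, edgeR adjusted p = 4.87e-05). edgeR called 12 higher, which adjustment over the list alone could not change. With size factors from the listed genes DESeq2 called 6 higher, against 12 with the recovered factors, and the lean was called in both (exact adjusted p = 0.0234 and 0.0256). The lean was lost at an authors' adjusted p under 0.01 (exact adjusted p = 0.0626) and above the median mean level (exact adjusted p = 0.0515). With replicate 1 as the only epl1ab-labelled library, 8 members were called and the lean was not (exact adjusted p = 0.0541); the calls there take their spread from Col-0 alone.

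Cold, jasmonate and clock genes went both ways. Of 18 cold and abscisic acid genes, 7 were listed lower and 4 higher (share lower, exact adjusted p = 0.000331; lean, exact adjusted p = 0.101). Against the genes of the fixed lists alone, the share lower was not called (38.9% against 27.0%, exact adjusted p = 0.335). COR15B and KIN2, cold-induced genes, fell 9.32-fold and 6.43-fold, while RAB18, a dehydrin also abundant in seeds, rose 8.14-fold with 372.2, 2144 and 5448 normalised reads in epl1ab-labelled replicates 1, 2 and 3. In replicate 1 alone against Col-0 the edgeR log2 fold change of RAB18 was 0.19, and without epl1ab-labelled replicate 3 it was 1.95 against 3.025 with all libraries; CBF2, also listed higher, was below 0 with size factors from the listed genes. Of 23 jasmonate genes 7 were higher and 2 lower, with JAZ8 5.73-fold and JAZ7 4.68-fold higher and AOC2, an enzyme of jasmonate synthesis, 3.22-fold lower by edgeR. The clock list had 4 of 20 genes higher and 1 lower. CCA1 and PRR9, which peak in the morning, rose 13.7-fold and 19.4-fold, and PRR3 fell 6.21-fold; PRR7, also listed higher, was below 0 with size factors from the listed genes. Neither the jasmonate nor the clock list leaned (exact adjusted p = 0.826 and 0.795). The share of jasmonate genes listed higher missed the threshold (exact adjusted p = 0.0515) and passed it among edgeR calls (exact adjusted p = 0.0233), and the share of clock genes listed higher passed above the median mean level alone (exact adjusted p = 0.0427, against 0.518 over all genes). edgeR called 7 cold and abscisic acid genes lower and 4 higher, 7 jasmonate genes higher and 2 lower, and 4 clock genes higher and 1 lower. Adjustment over each list alone could not change these counts. DESeq2 with size factors from the listed genes called 1 jasmonate gene higher and 2 lower. It called 1 cold and abscisic acid gene higher and 7 lower, and 3 clock genes higher and 1 lower. With the recovered factors its counts were those of edgeR. The size factors of the listed genes shift log2 fold changes by -1.11, so calls higher are lost by construction. Of the 7 jasmonate genes listed higher, 0 fell below 0, so the turned majority of calls does not bear on direction.

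Genes of flowering and of other organs were also among those listed higher. The authors listed 7 of 17 flowering time genes (share, exact adjusted p = 0.0102) and 4 of 8 floral organ identity genes (share, exact adjusted p = 0.0355) higher, and 0 of either lower. Against the genes of the fixed lists alone, neither share was called (exact adjusted p = 0.054 and 0.0803), nor was either above the median mean level (exact adjusted p = 0.468 and 0.717). The flowering time share was also lost with TMM factors and with size factors of the listed genes (exact adjusted p = 0.0725 and 0.234), and with replicate 1 as the only epl1ab-labelled library (exact adjusted p = 0.0598). TSF, a relative of the florigen FT, had 0 reads in Col-0 and 23 over the epl1ab-labelled libraries, at least 6.23-fold higher against 3 counts over the group. AP1, a floral meristem gene, rose 6.36-fold from 6 reads over Col-0 (edgeR adjusted p = 0.00109), and its edgeR log2 fold change went from 2.67 to 3.53 without Col-0 replicate 1. The floral organ genes AG, AP3, PI and SHP1 were those listed, together 123 ± 5.47 normalised reads in Col-0 (SD, n = 3) and 779, 585.4 and 847.7 in the epl1ab-labelled libraries. Of 21 root markers 4 were higher and 1 lower; edgeR called 4 higher, 2 without epl1ab-labelled replicate 2 and 1 with TMM factors. CASP5, a Casparian strip protein, was 3.98-fold higher and IRT1, the root iron transporter, 4.51-fold lower by edgeR. NRT2.1, a nitrate transporter, was 2.89-fold higher at the margin (edgeR adjusted p = 0.0497). It had 93.0, 15.04 and 17.08 normalised reads in Col-0 replicates 1, 2 and 3 against a mean of 123 ± 31.7 in epl1ab-labelled libraries (SD, n = 3), and without Col-0 replicate 1 its edgeR log2 fold change went from 1.53 to 2.93 (adjusted p = 0.000509). Its call was lost without Col-0 replicate 2 or 3 or any epl1ab-labelled replicate, without the count filter and with TMM factors (edgeR adjusted p from 0.0527 to 0.161). The neighbouring lists had few members in the tables: 3 of 24 glucosinolate genes higher and 1 lower, with CYP79F2 below 0 with size factors from the listed genes, and 3 of 9 type-A response regulators higher and 0 lower. Of 23 cell cycle and 14 auxin response genes, 0 were in the tables, and they are not analysed here. edgeR called 6 flowering time, 4 floral organ, 4 root, 3 glucosinolate and 3 response regulator genes higher, and 1 root and 1 glucosinolate gene lower. Adjustment over each list alone could not change these counts. DESeq2 with size factors from the listed genes called 3 flowering time, 3 floral organ, 0 root, 1 glucosinolate and 0 response regulator genes higher, against 7, 4, 4, 3 and 3 with the recovered factors.

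The higher and lower genes differed in size of change and in level. The median absolute log2 fold change in the authors' deposited table was 1.94 for genes listed higher and 1.45 for genes listed lower. The difference was 0.49 (permutation test over genes, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). That p describes the listed genes and does not measure the spread between libraries. Among genes above the median mean level the difference was 0.145, and it was 0.33 among edgeR calls and 0.26 among edgeR calls with replicate 1 as the only epl1ab-labelled library (permutation test, 10000 resamples, p = 0.0001 each, the smallest they can give). Genes listed higher had a median of 30.4 normalised reads in Col-0 and 134.5 in epl1ab-labelled libraries, against 1438 and 491.5 for genes listed lower. edgeR, run with the recovered scaling on the 4773 listed genes that passed its count filter, called 3012 higher and 1761 lower at an adjusted p under 0.05, all in the direction of the authors' deposited table. These genes were selected on the same libraries, so the refit is not independent evidence. Of the edgeR calls 63.1% were higher. DESeq2 with the recovered factors called 3519 higher and 1806 lower, or 66.1% higher. DESeq2 with size factors from the listed genes called 1585 higher and 1806 lower, or 46.7% higher; those factors shift log2 fold changes by -1.11 and put 294 of the genes listed higher below 0. Among named genes, YAF9B, HY5, CGA1, AP1, CASP5, NRT2.1, RAB18, JAZ8 and GSTU25 were not called with these factors, at log2 fold changes from 0.04 for HY5 to 1.84 for RAB18. The leans of the electron transport, Calvin cycle and plastid housekeeping lists were not called either (exact adjusted p = 0.0596, 0.0596 and 0.106). The difference in median size then reversed, from 0.49 in DESeq2 with the recovered factors to -1.04, and with TMM factors of the listed genes, which shift log2 fold changes by -0.47, from 0.33 to -0.60 in edgeR.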

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

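TMM factors of the listed genes and replicate 1 alone were settings added after seeing the data. Among genes above the median mean level, 1283 genes were listed higher and 1382 lower. There 5 in place of 9 lists leaned lower and 7 in place of 32 plastid genes were lower. Fewer genes were tested by construction, and a larger share of them was lower. The electron transport and Calvin cycle lists kept 6 lower and 0 higher members each and lost the lean against that share. A lean higher was easier to reach against it. DESeq2 with size factors of the listed genes called 1585 genes higher, against 3519 in DESeq2 with the recovered factors and 3012 in edgeR with its count filter. It left 3 in place of 8 lists over-represented among higher genes, the 8 being those of DESeq2 with the recovered factors too, and turned the difference of median absolute log2 fold change to -1.04. With TMM in edgeR that difference was -0.60, and 4 in place of 2 lists leaned higher, the salicylic acid defence and oxidative stress lists being added. Both settings lower log2 fold changes as a whole. By construction this moves that difference towards lower genes and removes genes called higher. The cause of the other changes was not separated further. At an authors' adjusted p under 0.01, 1 list leaned higher, and the cause was not tested. Against the genes of the fixed lists alone, 4 lists were over-represented among higher genes and 6 in place of 9 among lower genes; the background then holds many of the changed genes by construction. The shares no longer called there were those of flowering time, floral organ, heat shock and senescence genes among higher genes, and of electron transport, Calvin cycle and cold genes among lower genes (exact adjusted p = 0.0531, 0.824 and 0.335 for the last group). A threshold of 1 on the absolute log2 fold change removed no gene and so tests nothing, and no pseudocount was varied, since the values are counts. Leaving out any 1 library moved none of the counts of called genes over all genes or within a list by over 1.5 times, except that 2 in place of 4 root markers were called higher without epl1ab-labelled replicate 2. With replicate 1 as the only epl1ab-labelled library, that library is assumed to vary like the Col-0 libraries, so a call lost there does not separate level from missing replication. With the replicate block edgeR called 2992 genes higher and 1758 lower, and no call of a list or a named gene was lost. Deviations from the group means correlated at -0.30, -0.05 and -0.23 between libraries with the same number. Not every library correlated best with its own number. The deviations of epl1ab-labelled replicate 1 ran against those of replicates 2 and 3 (correlations -0.907 and -0.945). The values between groups mainly follow that contrast, so they cannot tell whether the numbers pair the libraries. Few reads stand behind 4 of the named plastid genes, with 50, 85, 100 and 74 reads over the Col-0 libraries for psbK, psbF, rpl32 and rps4.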

Other observations

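The tests in this part were chosen after the results had been seen, except that the bounds for 2 tests, on the neighbours of EPL1B and on the ratio of seed genes between replicates 2 and 3, were written before their values were computed. Families were taken from words in the deposited gene descriptions, long non-coding RNAs from the annotation's gene types, and phosphate starvation and clock genes from lists of loci drawn up by name; each was set against all other listed genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 18 families). Pentatricopeptide repeat proteins, which process organelle transcripts, had 104 genes listed lower and 5 higher (exact adjusted p = 2.63e-42), and tRNA ligases had 11 lower and 1 higher (exact adjusted p = 0.000141). Proteins described as chloroplastic had 375 lower and 34 higher (exact adjusted p = 2.33e-143). Proteins described as mitochondrial had 59 lower and 31 higher (exact adjusted p = 4.29e-09). Families taken from descriptions can share genes with each other and with the fixed lists, so their tests are not separate results. AT1G07590, for one, is in both the pentatricopeptide repeat and the mitochondrial family. Phosphate starvation genes had 13 lower and 1 higher of 16 looked up (exact adjusted p = 2.61e-05). Among these IPS1, a non-coding RNA of the phosphate response, went from 886 ± 404 to 18.9 ± 18.1 normalised reads, and SQD1, of sulfolipid synthesis, from 12793 ± 1716.5 to 2928 ± 215 (SD, n = 3 per group); RNS1 was the 1 listed higher.

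On the higher side stood 26 WRKY factors with 0 lower (exact adjusted p = 8.73e-05) and 19 NAC domain proteins with 0 lower (exact adjusted p = 0.0015), although 3 of each were below 0 with size factors of the listed genes. Receptor kinases had 67 higher and 8 lower, cytochrome P450 proteins 55 higher and 11 lower, and defensin-like proteins 25 higher and 1 lower (exact adjusted p of 2.61e-05, 0.0036 and 0.00108); of those higher, 5, 5 and 1 were below 0 with these size factors. Late embryogenesis abundant proteins had 24 higher and 0 lower (exact adjusted p = 0.000207), and this family holds seed genes. Long non-coding RNAs had 113 higher and 32 lower (exact adjusted p = 0.0036), with 3 of those higher below 0 with these size factors. F-box proteins, with 62 higher and 18 lower, and lipid transfer proteins, with 21 higher and 3 lower, lay near the threshold (exact adjusted p = 0.041 and 0.0404), and 3 and 2 of those higher were below 0 with these size factors. MADS-box proteins, glutathione S-transferases and disease resistance proteins did not pass (exact adjusted p = 0.114 each). Morning-phased clock genes, 4 higher and 0 lower of 9 looked up, did not pass either (exact adjusted p = 0.307), with PRR7 below 0 with these size factors; of 8 evening-phased genes 1, PRR3, was listed, too few to test.

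EPL1B was higher and EPL1A lower in the epl1ab-labelled libraries. Reads shared between these paralogs are argued against, since EPL1A had a log2 fold change of -1.56 where sharing would raise it, and the genes had 0 words of 50 bases in common. By these 2 genes alone, exchanged group labels cannot be told apart from the labels as given, since EPL1B at 4.57 and EPL1A point opposite ways. An exchange would make wild type the libraries with 205423 and 297887 summed normalised reads of seed maturation genes, epl1ab-labelled replicates 2 and 3. It would also make wild type the group with the lower chloroplast lists. No wild-type seedlings from outside the series were used to weigh this. An insertion that drives transcription at EPL1B stays open, and the allele is not described in the sources used here. Of its 10 nearest annotated genes 0 were listed higher and 2 lower, which decides nothing: 12.3% of protein-coding genes outside the NuA4 list were listed higher, so a low count is to be expected with or without an insertion.

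Seed maturation genes were high in epl1ab-labelled replicates 2 and 3 and far lower in replicate 1. Their sum of 1175.5 normalised reads in replicate 1 still lay above the Col-0 sums of 411, 374.9 and 43.9. A wild-type library in place of replicate 1 is argued against by its 17029 normalised reads of EPL1B, and depth by scaling factors that differ from those of replicates 2 and 3 by at most 1.11-fold. A varying amount of seed-stage tissue from one source would keep the genes in one ratio between replicates 2 and 3 if all their reads came from it. The SD of that log2 ratio was 0.56 over 16 genes, at percentile 98.2 of 10000 random lists matched on level (median 0.27). Reads from other tissue, which these counts do not separate, could also spread the ratio, so this SD does not decide against one source. Seed-stage tissue of different ages, and a genotype that acts on seed genes in some plants or experiments, were not tested and stay open.

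The chloroplast lists were lower in all 3 epl1ab-labelled libraries. Seed-stage tissue in place of green tissue is argued against by the 131 listed members of 9 lists. Their median log2 ratio to the Col-0 mean was -1.51 in replicate 1, against -1.690 and -1.685 in replicates 2 and 3. Seed genes summed to 1175.5 normalised reads in replicate 1, against 205423 and 297887 in replicates 2 and 3. The authors' scaling cannot be told apart from a fall in absolute level, since one factor per library moves every gene alike; 9 of the 9 lists leaned lower with TMM factors and 6 with size factors of the listed genes. The genotype stays open as a biological explanation, untested beyond the labels. Of the 10 splits of the 6 libraries, 1, the labelled one, called 4773 genes by edgeR and the highest other called 75; with 10 splits a share under 0.05 cannot be reached, and the genes had been selected on the labelled split.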
